A study of Homo sapiens with 10 samples.

How the data were processed

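RNA-seq of MCF-7 cells was deposited for total input RNA, polyA-depleted RNA, polyA-enriched RNA and 2 knockdowns. One table of average RPKM values for input and polyA-depleted RNA was used, and the other 6 of the 10 samples were not analysed here. Per the labels' protocols the input RNA came from a pre-cleared nuclear extract kept as a control for RNA immunoprecipitation, in 2 biological replicates. The labels of the polyA-depleted samples give 2 replicates and do not say that they came from separate cultures, so p-values measure the spread between these libraries, which may be technical. Per the submitters' processing notes, FastQC and TopHat2 2.0.12 were used with the hg19/GRCh37 build. The read counter, the annotation release, the handling of reads that map to several copies and the strand setting are not given in the sources used here. Without strand, reads of a feature and of an overlapping transcript, host introns and exons included, cannot be told apart.

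The unit is RPKM, averaged by the authors over the libraries of a group, per the file headers. Each feature has a name, coordinates, a strand and a length in the deposited table, and the length equals the end minus the start plus 1 base. Of 193 symbols found in GENCODE v29, 189 were 1 base longer in the table than in that annotation, which alters an RPKM by at most 1.85% and alters both groups alike. Coordinates are given as listed. The annotation used here is on GRCh38, so it served only for names, lengths and host genes, and no coordinate was converted. Of 40 named features, 38 matched 1 annotated gene by symbol and length, 28 of these lay inside a longer gene on the same strand, 12 of them in introns and 16 overlapping an annotated exon. Of the 290 features, 22 carry the name of a host RNA and 1 that of a microRNA, MIR3607. Of these 23, 15 were named as a snoRNA or scaRNA where length, strand, chromosome and the exact spacing to the nearest feature matched by name (up to 5000000 bases away) fitted 1 annotated gene, such as SNORA73A for a feature listed under SNHG3, and 8, MIR3607 among them, kept the name in the table. That naming was added after the data were seen.

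The product of RPKM and length was a sum of whole multiples of 2 steps in each column, so whole reads of both libraries of a group could be recovered for 290 of 290 features in both groups, with a tolerance of 1e-07 reads for a value called whole. The divisors are 28337803 and 18135271 reads in input and 88639073 and 71261927 reads in polyA-depleted RNA. On simulated averages the same procedure recovered 290 of 290 features, and it solved 0 of 224 input and 0 of 249 polyA-depleted values to which noise had been added. A feature of 130 bases with 1 read has an RPKM of 0.271 and 0.424 in the input libraries and of 0.0868 and 0.108 in the polyA-depleted libraries. Which recovered library is which replicate is unknown, so they are called deeper and shallower, and nothing is paired.

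Features with a mean RPKM of 1 or more over the 2 columns were compared (140 of 290) by log2((polyA-depleted RPKM + 1) / (input RPKM + 1)), which understates the change of features with low values. Because the table has 1 average per group, the design fixed before the data were examined made no test of these ratios. For lists with at least 4 compared features the median was set against 10000 random lists of the same size matched on mean RPKM in 10 bins, as a description of these libraries. In a check with simulated values, 10 of 100 unchanged lists fell below the 5 or above the 95 percentile and a raised list reached 100.

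A test was added after the data were seen. limma 3.58.1 (lmFit and eBayes with trend, R 4.3.3) compared log2(RPKM + 1) of the 2 recovered input libraries with the 2 recovered polyA-depleted libraries over the 140 features, two-sided with Benjamini-Hochberg adjustment and a threshold of 0.05. Camera tested lists of 5 or more compared members with a preset correlation of 0.01 and with an estimated one. On simulated libraries of input and polyA-depleted RNA with 140 features, limma called 80% of features changed 4-fold, 95% of those changed 8-fold and 100% of those changed 16-fold, and 2 of the 80 unchanged features beside them (2.5%). Where nothing had been changed it called 0 of 140, with 11 at an unadjusted p under 0.05. Unchanged features were simulated at their polyA-depleted level in both groups, which is mostly above the real input level. Error rates for unchanged features at the real input depth, with nearly all features raised, or after centring were not simulated. Rate ratios of recovered reads per divisor have exact 95% intervals, and a fold against 0 input reads is a lower bound against 3 reads over the input group. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

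The rule for named features, fixed before the data were examined, took the 10 largest log2 ratios among features with a mean RPKM of 10 or more (no feature there was lower in polyA-depleted RNA), the 10 highest values per group, every listed member of the lists of pre-ribosomal RNA processing, PARP-1-linked H/ACA snoRNAs, major and minor spliceosomal snRNAs and other abundant nuclear RNAs, and the members with the highest and lowest ratio of each remaining list. The remaining lists were C/D snoRNAs, H/ACA snoRNAs, scaRNAs, own promoters, the hosts GAS5 and SNHG1, ribosomal protein hosts and the imprinted clusters of 15q11 and 14q32. Alternatives fixed beforehand were pseudocounts of 0.1 and 10, no filter or a mean RPKM of 10 or more, centring on the median, scaling to equal sums, random lists without matching, and shares without the 5 features of highest mean RPKM. Alternatives added later were a filter on input RPKM, equal sums for the lists, the names as the table gives them, leaving out each recovered library, limma without trend, limma voom, and centring together with these settings. A fit without 1 library leaves a lone library in its group, which is assumed to vary like the other group. For compared features without any input read the input group does not vary, so passing a fit without 1 polyA-depleted library says nothing about their stability.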

Results

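Expression of small nucleolar RNAs (snoRNAs), small Cajal body RNAs (scaRNAs) and small nuclear RNAs (snRNAs) was measured by RNA-seq in MCF-7 cells, an established human breast cancer cell line. The series holds 10 samples in 5 groups of 2. The groups are total input RNA taken from a pre-cleared nuclear extract, polyA-depleted RNA, polyA-enriched RNA, and cells with knockdown of luciferase (a control) or of the RNA helicase DDX21. Values for the 4 input and polyA-depleted samples were analysed. The other 6 samples were not analysed here, so the level of DDX21 was not checked. The table listed 290 features, 54 to 421 bases long, with 1 average RPKM (reads per kilobase of feature length, scaled to the reads of the library) per group. These averages had been divided by 28337803 and 18135271 reads in the input libraries and by 88639073 and 71261927 reads in the polyA-depleted libraries. The listed features took 4601 and 2789 of the input reads, and 145641 and 125167 of the polyA-depleted reads. The libraries of each group are called deeper and shallower below, since the averages carry no replicate numbers.

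The comparison of input with polyA-depleted RNA asked which snoRNAs and snRNAs these cells expressed. On the authors' RPKM scale, 138 of the 140 features with a mean RPKM of 1 or more were higher in polyA-depleted RNA, and 121 had a log2 ratio of 1 or more, or 44 with a pseudocount of 10. The H/ACA snoRNAs SNORA73A and SNORA73B, which act in the processing of pre-ribosomal RNA, reached the highest levels, at 2012 and 1020 RPKM in polyA-depleted RNA against 90.8 and 34.0 RPKM in input. The median log2 ratio of the 140 features was 2.08, with quartiles of 1.41 and 2.90, and their median RPKM was 1.23 in input and 9.58 in polyA-depleted RNA. The median log2 ratio was 0.77 with a pseudocount of 10, 0.84 with no filter and 3.29 at a mean RPKM of 10 or more. All 38 features with a mean RPKM of 10 or more were higher. The 2 features that were lower, named after their values were seen, were RNU1-60P, a U1 snRNA pseudogene, at 4.90 against 4.20 RPKM, and MIR3607, at 1.10 against 0.922 RPKM. Their direction was not stable. In limma on the recovered libraries their log2 changes were -0.22 and 0.072 (adjusted p = 0.686 and 0.928). Without 1 library these ranged from -0.52 to 0.091 for RNU1-60P and from -0.77 to 0.91 for MIR3607. Both polyA-depleted libraries lay above both input libraries for 128 of the 140 features. For a single feature chance gives 16.7%, but the features share the same 4 libraries and a shift of the whole table, so the count cannot be set against that share. In limma on the library values recovered from the averages, 102 features rose and 0 fell past an adjusted p of 0.05, and at an unadjusted p under 0.05 the counts were 110 and 0. With limma voom on the recovered reads the counts were 79 and 0, and in limma on the RPKM of all 290 features they were 32 and 2. Without 1 library the median log2 change of the 140 features in limma ranged from 1.824 to 2.304. For the 9 compared features without an input read, SNORD18B and SNORD110 among them, both input values are 0. A fit without 1 polyA-depleted library then has no spread left within either group, so passing it cannot show that their calls are stable.

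**Figure D1:**
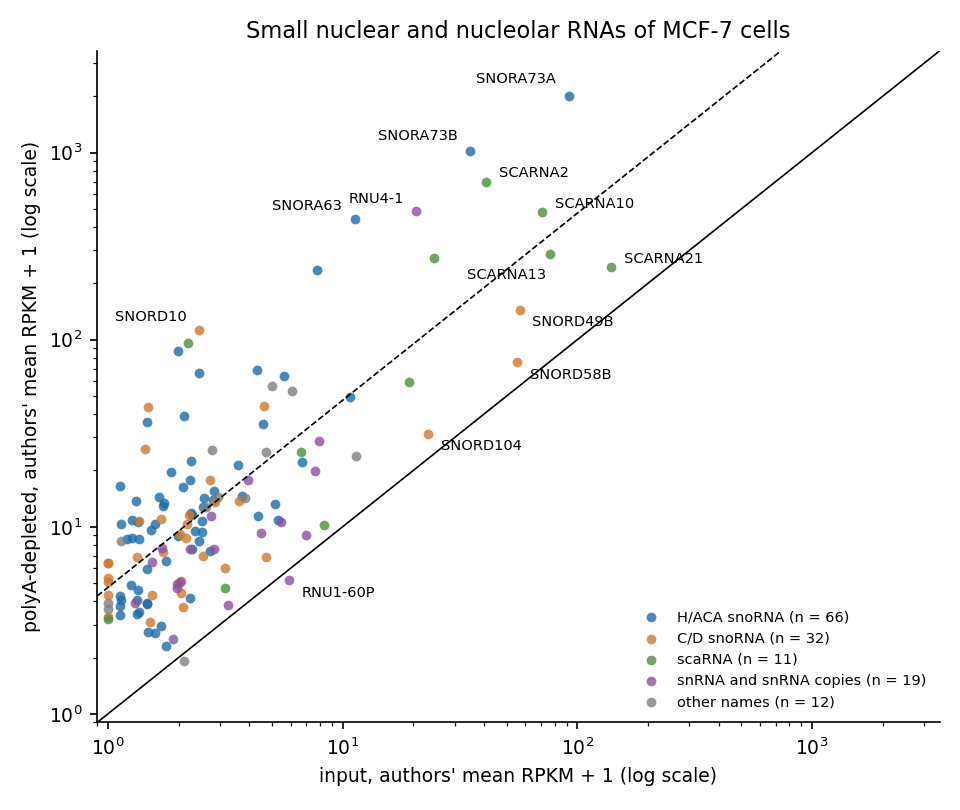
Authors' mean RPKM + 1 of 140 features in input (x axis, log scale) and polyA-depleted RNA (y axis, log scale) of MCF-7 cells, coloured by class; the solid line marks equal values and the dashed line the common shift of 2.25 on the log2 scale. Nearly all points, 138 of 140, lie above the solid line, and SNORA73A lies highest at 2012 RPKM in polyA-depleted RNA.

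These ratios share a shift of the whole table, since the medians of the 2 columns differed by 2.25 on the log2(RPKM + 1) scale. This common shift lies above the median log2 ratio of 2.08, so features below it can still lie above the median feature. On this scale a single factor would also raise abundant features more than scarce ones. Relative to that shift 62 of the 140 features lay above it, and after scaling both columns to the same summed RPKM 63 were higher in polyA-depleted RNA. With each library centred on its median, 11 features rose and 2 fell in limma past an adjusted p of 0.05, with 21 and 19 at an unadjusted p under 0.05. With equal sums the counts were 15 and 14. After centring the 11 were SNORA73A, SNORA73B, SNORA63, SNORA12, SNORA70, SNORA71A, SNORA22, SNORD10, SNORD102, SCARNA2 and SCARNA5. The 2 that fell relative to the shift were the snRNA pseudogenes RNU6-925P and RNU1-60P, of which RNU6-925P was higher on the authors' scale, at 5.99 RPKM in input and 8.09 RPKM in polyA-depleted RNA. After centring, the count past the threshold was 0 without either the deeper or the shallower input library, 29 without the deeper polyA-depleted library, 27 without the shallower one, and 0 with limma voom.

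Of the 10 features with the highest RPKM in input, 7 were also among the 10 highest in polyA-depleted RNA. SCARNA21, an intronic RNA of CHD3, led the input column with 138 RPKM and reached 243 RPKM in polyA-depleted RNA, a log2 change of 0.82 ± 0.21 (SE, adjusted p = 0.00940 in limma), a call that ended when any 1 of the 4 libraries was left out (adjusted p from 0.0577 to 0.140). Its log2 ratio was -1.44 relative to the common shift. SNORA73A followed in input and led the polyA-depleted column. It is listed on chromosome 1 from 28833877 to 28834083 on the plus strand of hg19, overlaps an annotated exon of SNHG3 and an intron of RCC1, and changed by 4.46 ± 0.14 on the log2 scale (SE, adjusted p = 3.24e-07 in limma). Its neighbour SNORA73B, from 28835070 to 28835274, changed by 4.82 ± 0.28 (SE, adjusted p = 8.96e-06 in limma). They are near-identical copies, so the split of reads between them is uncertain. SCARNA2, which has its own promoter, rose from 39.9 to 698 RPKM, and RNU4-1, a gene of the U4 snRNA, from 19.6 to 484 RPKM. SCARNA10 in an intron of NCAPD2 rose from 69.8 to 478 RPKM, SCARNA13 in an intron of SNHG10 from 75.4 to 286 RPKM, and SCARNA12 in PHB2 from 23.5 to 272 RPKM. SNORA63 in EIF4A2 rose from 10.2 to 442 RPKM and SNORA12 in an intron of CWF19L1 from 6.80 to 236 RPKM. Of these RNAs, only SCARNA13 and SCARNA21 lay below the common shift; after scaling to equal sums SCARNA10 did so too, at a log2 ratio of -0.45.

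**Figure D2:**
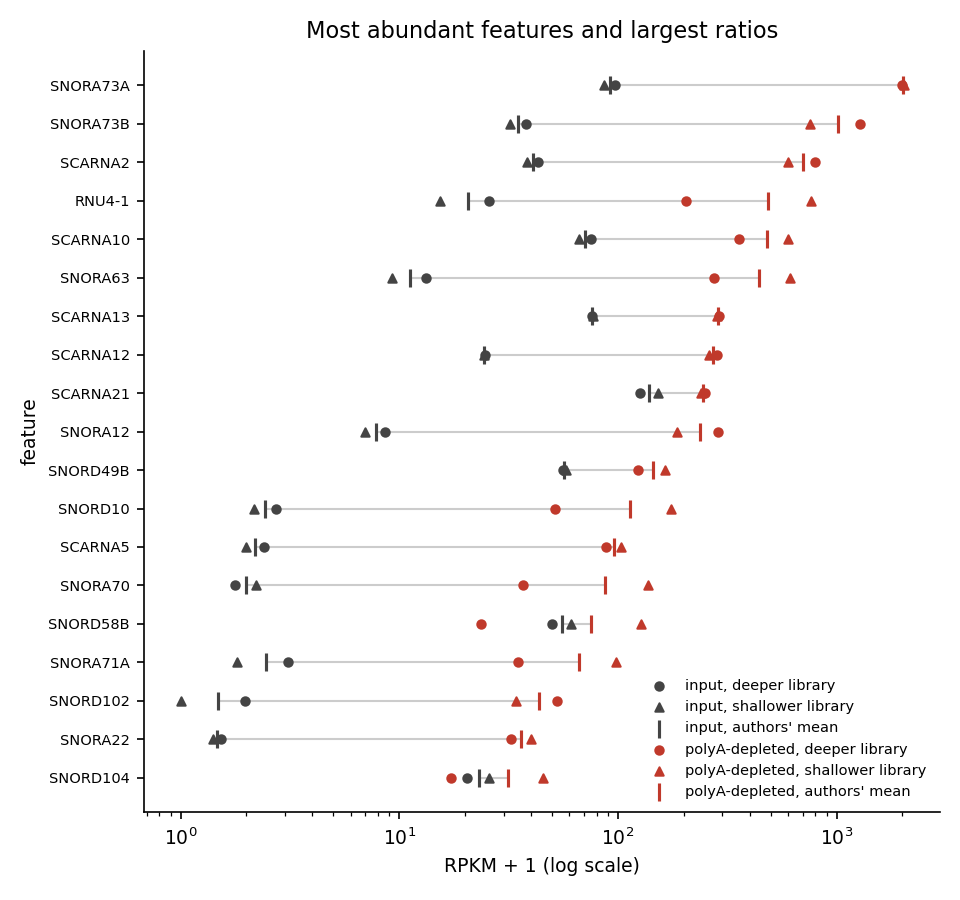
RPKM + 1 (x axis, log scale) of the features with the highest mean RPKM in each group or the largest ratios (y axis); circles and triangles are the deeper and shallower library of a group, ticks the authors' means, and grey lines join the means. For SNORD58B, at 22.7 and 126 RPKM, and SNORD104, at 16.2 and 44.7 RPKM, the polyA-depleted libraries lie on either side of the input libraries.

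The 10 largest log2 ratios among features with a mean RPKM of 10 or more rested on 2 to 330 input reads each. SNORD10, within EIF4A1, had the largest, 5.53, with 1.44 RPKM from 10 input reads against 112 RPKM from 2410 polyA-depleted reads, a rate ratio of 70.0 with a 95% exact interval of 38.0 to 146. It was followed by SCARNA5 in an intron of ATG16L1 with 5.45, SNORA70 in the ribosomal protein gene RPL10 with 5.45, SNORA63 with 5.30, SNORA12 with 4.92, SNORD102 in the ribosomal protein gene RPL21 with 4.88, SNORA73B with 4.87, SNORA71A with 4.75, SNORA22 with 4.63 and RNU4-1 with 4.56. All 10 rose in limma in the full fit, and without 1 library the lowest log2 change among them was 3.36, that of RNU4-1. For RNU4-1 the polyA-depleted libraries gave 204 and 763 RPKM, for SNORA70 35.8 and 136 RPKM, and for SNORD10 50.3 and 174 RPKM. The first rank of SNORD10 is therefore not settled. Its log2 change in limma was 5.29, against 5.45 for SCARNA5, and without the shallower polyA-depleted library it was 4.40, against 5.33 for SCARNA5. SNORA71A has near-identical copies in the table (SNORA71B, SNORA71C and SNORA71D), so its reads are uncertain. The rows SNORA22.2 and SNORA22.3 carry the family name of SNORA22, so its reads may be uncertain too.

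Among the H/ACA snoRNAs, most of which guide pseudouridylation of ribosomal RNA, 53 of 66 compared rose in limma past an adjusted p of 0.05, 54 when adjusted over the list alone, and 13 did not pass. The count was 33 without the deeper input library, 33 without the shallower one, 15 with no filter (24 when adjusted over the list alone), 7 after centring and 6 with equal sums, where 2 fell and 0 passed in either direction when adjusted over the list alone (9 higher and 5 lower at an unadjusted p under 0.05). Their median log2 ratio was 2.33, at the 99.8 percentile of 10000 random lists matched on mean RPKM (95% of these lay between 1.93 and 2.28). In limma's camera against the other features the list did not pass (adjusted p = 0.258 with a preset correlation and adjusted p = 0.862 with an estimated correlation). It passed with no filter on low values at the preset correlation (adjusted p = 0.00064) and not at the estimated one (adjusted p = 0.290 with an estimated correlation). Relative to the common shift the median was 0.085, with 35 members above and 31 below, and after scaling to equal sums it was 0.11. SNORA73A, SNORA73B and SNORA63 are examples that rose. SNORA50 was at 0.773 and 1.32 RPKM and did not pass (adjusted p = 0.490 in limma).

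Among the C/D snoRNAs, most of which guide 2'-O-methylation of ribosomal RNA, 23 of 32 compared rose in limma past an adjusted p of 0.05, also 23 when adjusted over the list alone, and 9 did not pass. The count was 9 without the deeper input library, 13 without the shallower one, 6 with no filter, 2 after centring and 7 with equal sums, where 4 fell. The median log2 ratio was 2.14, the 80.2 percentile of matched random lists, against 2.08 over all 140 compared features. It was -0.11 relative to the common shift, which lies above the median of all 140 features, and -0.15 after scaling to equal sums. SNORD49B, in the host RNA LRRC75A-AS1, rose from 55.9 to 143 RPKM (adjusted p = 0.00426 in limma), a call that ended without the deeper (adjusted p = 0.0632) or the shallower input library (adjusted p = 0.0610). SNORD58B, in the ribosomal protein gene RPL17, was at 54.5 RPKM in input and 74.5 RPKM in polyA-depleted RNA and did not pass (adjusted p = 0.991 in limma). Its polyA-depleted libraries held 135 and 603 reads, and its log2 change was 1.20 without the deeper of them and -1.22 without the shallower. Its direction is therefore not settled. SNORD104, in an intron of SNHG25, was at 22.1 and 30.4 RPKM (adjusted p = 0.614 in limma).

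Of the 11 compared scaRNA features, which guide modification of snRNAs, 8 rose in limma past an adjusted p of 0.05 and also when adjusted over the list alone. The count was 5 without the deeper input library, 5 without the shallower one, 2 after centring and 1 with equal sums, where 4 fell. Adjusted over the list alone, 6 passed after centring and 8 with equal sums, in both directions together. The median log2 ratio was 1.91, the 8.83 percentile of matched random lists, and -0.34 relative to the common shift and -1.08 after scaling to equal sums. SCARNA5 had the largest ratio, from 1.20 to 94.9 RPKM. The lowest was that of a feature of 81 bases listed under SCARNA9, at 7.32 and 9.20 RPKM (adjusted p = 0.786 in limma), whose log2 ratio was -0.47 without the deeper polyA-depleted library. SCARNA1 had 0 input reads and 54 polyA-depleted reads, which makes it at least 5.23-fold higher against a floor of 3 reads over the input group, and it did not pass (adjusted p = 0.0793 in limma).

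Of the 9 snRNA genes of the major spliceosome in the table, 4 rose in limma past an adjusted p of 0.05 and 3 when adjusted over the list alone. The median log2 ratio was 1.76, the 26.7 percentile of matched random lists, and it was 0.88 without the shallower polyA-depleted library, -0.48 relative to the common shift and -0.56 after scaling to equal sums. The count was 1 with no filter and 0 after centring or with equal sums, with 1 higher and 2 lower at an unadjusted p under 0.05 after centring and 0 and 2 with equal sums. RNU4-1, RNVU1-6 (1.74 to 10.5 RPKM), RNU1-1 (0.702 to 6.69 RPKM) and RNU5A-1 (0.537 to 5.47 RPKM) rose, and of these the call held in every fit without 1 library for RNU4-1 alone. It ended for RNVU1-6 without the shallower input library (adjusted p = 0.0883 in limma), for RNU5A-1 without either input library (adjusted p = 0.120 and 0.136) and for RNU1-1 in every such fit but the one without the deeper input library. RNVU1-18 was at 3.48 and 8.25 RPKM, RNU5B-1 at 1.24 and 6.62, RNU5E-1 at 0.975 and 3.92, RNU5F-1 at 0.299 and 2.91, and RNU5D-1 at 2.25 and 2.80, none past the threshold. Genes of U1, U4 and U5 snRNAs have near-identical copies, so these levels depend on how shared reads were assigned, which is not given in the sources used here. In the minor spliceosome, RNU12 rose from 6.89 to 27.8 RPKM (adjusted p = 0.0123 in limma, 1 gene also when adjusted over the list alone), while RNU11 was at 6.59 and 19.0 RPKM and RNU4ATAC at 4.45 and 9.59 RPKM (adjusted p = 0.109 and 0.0951 in limma). All 3 lay below the common shift, and below 0 after scaling to equal sums. The call of RNU12 held in 1 of the 4 fits without a library, the one without the deeper polyA-depleted library, and the others gave adjusted p values of 0.0572 to 0.198. The table had 0 rows for the other abundant nuclear RNAs of the fixed lists, RN7SK and RNU7-1.

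**Figure D3:**
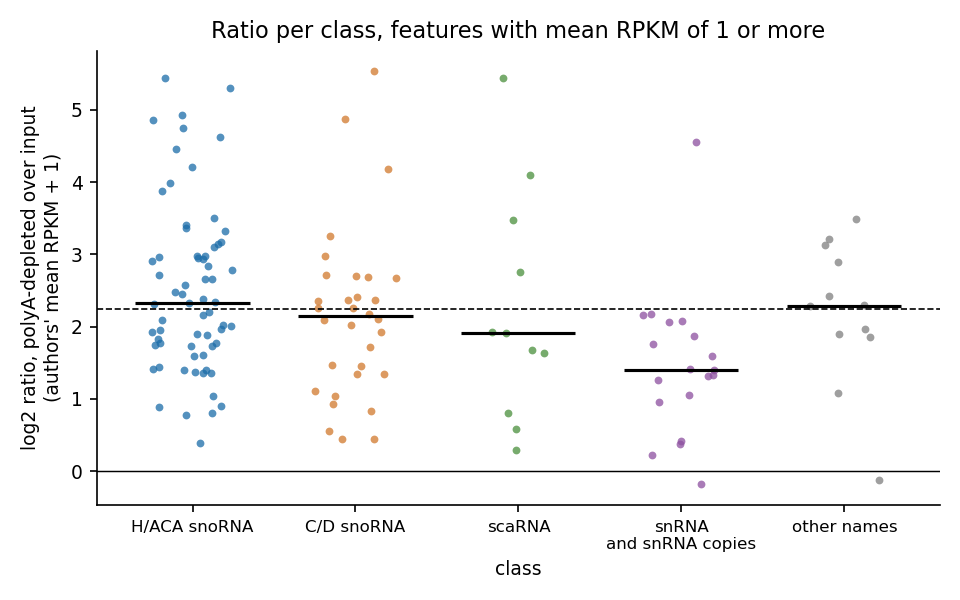
Log2 ratio of polyA-depleted over input (y axis, authors' mean RPKM + 1) for each of the 140 compared features by class (x axis); bars are class medians, the solid line marks 0 and the dashed line the common shift of 2.25. The H/ACA median of 2.33 lies above the dashed line, the C/D and scaRNA medians of 2.14 and 1.91 below it. The median of all 140 features, 2.08, also lies below the dashed line.

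All 5 snoRNAs of pre-ribosomal RNA processing in the table rose in limma past an adjusted p of 0.05, 5 also when adjusted over the list alone, with a median log2 ratio of 2.37 (the 54.9 percentile of matched random lists). The count was 3 with no filter, 2 after centring and 2 with equal sums. They were SNORA73A, SNORA73B, SNORD13 (1.03 to 8.14 RPKM), SNORD14D in HSPA8 (0.714 to 6.33 RPKM) and SNORD118 in TMEM107 (0.335 to 5.90 RPKM). Relative to the common shift SNORD13 and SNORD14D turned to -0.074 and -0.15, and after scaling to equal sums they were at -0.20 and -0.065. The calls of SNORD13, SNORD14D and SNORD118 ended without the deeper input library (adjusted p = 0.0507, 0.0507 and 0.114 in limma), and those of SNORD14D and SNORD118 also without the shallower one (adjusted p = 0.0607 and 0.0886). The list of own promoters, SNORD13, SNORD118 and SCARNA2, had 3 of 3 members rise, 3 also when adjusted over the list alone.

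The H/ACA snoRNAs that the study links to PARP-1, as recalled before the data were examined, were SNORA18, SNORA37, SNORA73A, SNORA73B and SNORA74A. The study may have chosen them on these samples, so their direction is not independent evidence. All 4 that could be compared rose in limma past an adjusted p of 0.05, 4 also when adjusted over the list alone, with a median log2 ratio of 3.59 (the 84.1 percentile of matched random lists), and with no filter 2 of all 5 rose. SNORA74A rose from 0.582 to 9.39 RPKM and SNORA18 in TAF1D from 1.43 to 7.35 RPKM, of which SNORA18 turned to -0.47 relative to the common shift and -0.74 after scaling to equal sums. The rows SNORA74.4 and SNORA74B carry the family name of SNORA74A, so its reads may be uncertain. The call of SNORA74A ended without the shallower polyA-depleted library (adjusted p = 0.142 in limma) or the shallower input library (adjusted p = 0.0663), and that of SNORA18 held only without the shallower input library, with adjusted p values of 0.0934 to 0.180 in the other 3 fits. SNORA37, in an intron of MBD2, stayed under the mean RPKM minimum, with 0 input reads and 15 polyA-depleted reads, all of them in the shallower library.

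By host gene, 10 of the 11 compared snoRNAs on the fixed list of ribosomal protein hosts rose in limma past an adjusted p of 0.05, 10 also when adjusted over the list alone. That list does not hold every snoRNA of such genes, and SNORD102 in RPL21, for example, is not on it. The median log2 ratio of the 11 was 2.11 (the 38.4 percentile of matched random lists), or 2.02 with the 2 members without input reads at their lower bound. Without the shallower polyA-depleted library the log2 change of SNORD58B was -1.22. The count past the threshold was 1 after centring and 3 with equal sums, where 1 fell. With no filter on low values it was 0 of 11, with 9 at an unadjusted p under 0.05 and 9 when adjusted over the list alone. On this list SNORA70 was the highest, and SNORD58B alone did not pass in the full fit. The median was -0.14 relative to the common shift, and after scaling to equal sums it was 0.70. SNORD27 (1.72 to 16.8 RPKM) and SNORD28 (0.363 to 9.76 RPKM), both overlapping annotated exons of SNHG1, rose, 2 of 2 also when adjusted over the list alone, and SNORD28 lost its call without the shallower polyA-depleted library (adjusted p = 0.0952 in limma). No row matched the fixed GAS5 snoRNAs or the imprinted cluster of 14q32 by name. The imprinted cluster of 15q11 had 1 row, SNORD116-18, with 2 input reads and 18 polyA-depleted reads, all 18 in the deeper library.

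Within the listed RNAs, H/ACA snoRNAs held 25.8% of the summed RPKM in input and 55.5% in polyA-depleted RNA, a measure that does not depend on the scaling of the columns. The scaRNAs held 43.0% in input and 26.0% in polyA-depleted RNA, and C/D snoRNAs 18.6% and 7.82%. For these 3 classes the 2 libraries of a group lay closer to each other than to the other group, at 27.3% and 24.3% against 57.9% and 53.5% for H/ACA snoRNAs. The snRNA rows held 8.69% in input and 7.76% in polyA-depleted RNA, and the polyA-depleted libraries, at 4.38% and 10.7%, lay on either side of the input libraries. The 5 most abundant features of each column held 48.3% of the summed RPKM in input and 56.2% in polyA-depleted RNA, and with the 5 features of highest mean RPKM left out the H/ACA share was 16.5% in input and 43.9% in polyA-depleted RNA. No test of these shares was run, and an exact permutation test of 2 libraries against 2 cannot reach 0.05.

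**Figure D4:**
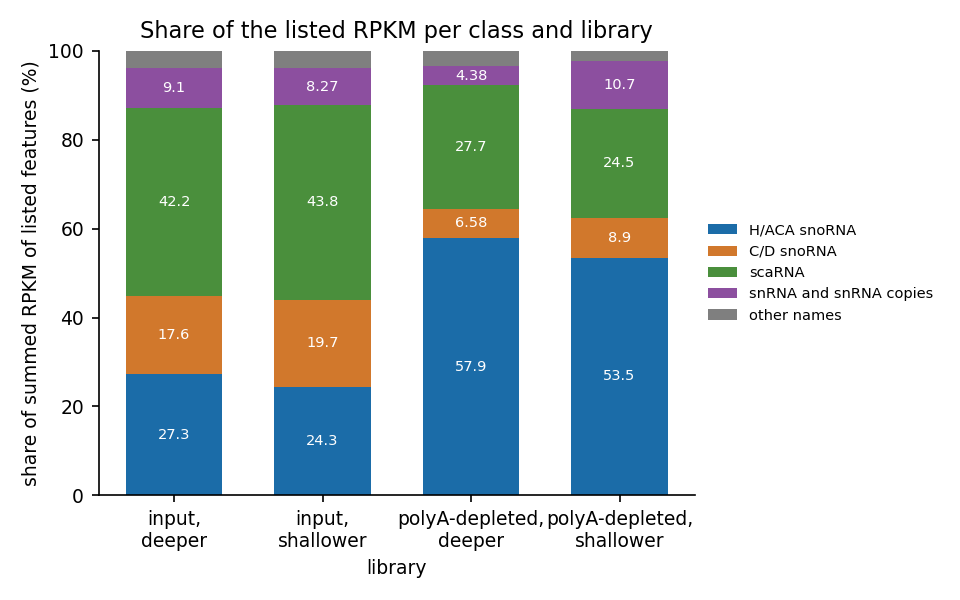
Share of the summed RPKM of the 290 listed features (y axis, percent) held by each class in the 4 libraries (x axis). H/ACA snoRNAs hold 27.3% and 24.3% in the input libraries and 57.9% and 53.5% in the polyA-depleted libraries.

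Depth limited the input side, where 87 of the 140 compared features had fewer than 10 reads over both libraries. For 9 compared features without any input read the polyA-depleted value was at least 2.52 to 6.10 times the floor of 3 input reads, and intervals and floors cover counting error only.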

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

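The fits on recovered libraries, the fits without 1 library, the filter on input RPKM, equal sums for the lists, the names as the table gives them and centring combined with another setting were chosen after the data were seen. No paired analysis was possible because the columns are group averages and the recovered libraries carry no replicate numbers. Of the 138 features higher in polyA-depleted RNA, the count was 208 of 290 with no filter, 38 of 38 at a mean RPKM of 10 or more and 80 of 83 at an input RPKM of 1 or more, which follows from the number of features kept, and 62 after centring and 63 with equal sums. It was 136 to 138 without 1 library. The count at a log2 ratio of 1 or more was 44 with a pseudocount of 10, 35 at a mean RPKM of 10 or more, 68 at an input RPKM of 1 or more, 23 after centring and 33 with equal sums. The median log2 ratio was 2.90 and 0.77 with pseudocounts of 0.1 and 10, 0.84 with no filter, 3.29 at a mean RPKM of 10 or more, 1.81 to 2.27 without 1 library, and it reversed to -0.19 with equal sums. With a pseudocount of 0.1 the list medians were 2.94 for C/D snoRNAs, 3.18 for H/ACA snoRNAs, 2.52 for major snRNAs, 3.79 for pre-ribosomal RNA processing and 3.89 for ribosomal protein hosts. With a pseudocount of 10 they were 0.62, 0.87, 0.55, 0.72 and 0.71 in that order, and 1.28 for scaRNAs. With no filter they were 1.34 for C/D snoRNAs, 1.78 for H/ACA snoRNAs and 0.58 for scaRNAs. At a mean RPKM of 10 or more they were 3.26 for C/D snoRNAs, 4.21 for H/ACA snoRNAs, 2.34 for scaRNAs, 4.56 for major snRNAs (RNU4-1 alone), 4.66 for pre-ribosomal RNA processing and 4.09 for ribosomal protein hosts. Centring reversed C/D snoRNAs to -0.11, scaRNAs to -0.34, major snRNAs to -0.48 and ribosomal protein hosts to -0.14, and left H/ACA snoRNAs at 0.085 and pre-ribosomal RNA processing at 0.12. Equal sums reversed C/D snoRNAs to -0.15, scaRNAs to -1.08 and major snRNAs to -0.56, and left H/ACA snoRNAs at 0.11, pre-ribosomal RNA processing at 0.64 and ribosomal protein hosts at 0.70. Without 1 library the medians ranged over 1.77 to 2.27 for C/D snoRNAs, 1.96 to 2.57 for H/ACA snoRNAs, 0.88 to 1.97 for major snRNAs, 2.01 to 3.08 for pre-ribosomal RNA processing and 2.17 to 2.36 for ribosomal protein hosts. Without matching on expression the percentile was 63.8 for C/D snoRNAs and 27.9 for scaRNAs. Without the 5 most abundant features the input and polyA-depleted shares were 26.0% and 17.8% for C/D and 16.5% and 43.9% for H/ACA snoRNAs. At a mean RPKM of 10 or more the input shares were 23.7% for H/ACA snoRNAs, 49.9% for scaRNAs and 4.44% for snRNAs, and the polyA-depleted scaRNA share was 28.5%. With names as the table gives them the shares were 11.5% and 5.16% for C/D and 14.6% and 30.7% for H/ACA snoRNAs, because 6 C/D and 8 H/ACA snoRNAs listed under a host name, SNORD49B and SNORA73A among them, are then outside both classes. The 102 features past an adjusted p of 0.05 became 34 of 290 with no filter (32 higher, 2 lower), 35 of 38 at a mean RPKM of 10 or more, 13 after centring (11 higher, 2 lower) and 29 with equal sums (15 higher, 14 lower). They were 97 and 80 with pseudocounts of 0.1 and 10, 101 without trend, 79 with voom, and 54 to 96 without 1 library. Relative to the common shift the 13 features became 6 with a pseudocount of 0.1, 15 with a pseudocount of 10, 0 with limma voom (26 at an unadjusted p under 0.05), and 0 to 29 without 1 library (15 to 55 unadjusted). In limma's camera no list passed an adjusted p of 0.05 over the 140 features with either correlation (0.258 to 0.830 preset, 0.862 estimated). With no filter and the preset correlation H/ACA snoRNAs (0.00064), pre-ribosomal RNA processing (0.0153), C/D snoRNAs (0.0212) and ribosomal protein hosts (0.0212) passed as higher, and H/ACA snoRNAs passed with centring and voom (0.0333); with an estimated correlation none of these passed (adjusted p = 0.290 for the 4 lists with no filter and 0.659 with centring and voom). With no filter the members that rose past an adjusted p of 0.05 were 15 H/ACA snoRNAs, 6 C/D snoRNAs, 6 scaRNAs and 0 of the ribosomal protein hosts, against 53, 23, 8 and 10 over the 140 features. Among the named features, centring reversed SCARNA13 to -0.34, SCARNA21 to -1.44, SNORD49B to -0.90, SNORD58B to -1.80, SNORD104 to -1.80, RNU12 to -0.38, RNU11 to -0.85, RNVU1-6 to -0.18, RNU4ATAC to -1.29, SCARNA9 to -1.95, RNVU1-18 to -1.20, SNORD13 to -0.074, SNORA18 to -0.47, RNU1-1 to -0.069, RNU5B-1 to -0.48, SNORD14D to -0.15, RNU5A-1 to -0.17, RNU5E-1 to -0.93, RNU5F-1 to -0.65, RNU5D-1 to -2.02, SNORA50 to -1.86 and SNORA37 to -1.39, by construction of the shift. The pseudocount of 1 pulls down the ratios of features with low values, so a negative centred value need not mean a smaller fold than that of the whole table. After scaling to equal sums RNU1-1 (0.018), RNU5A-1 (0.088), RNU5F-1 (0.034) and SNORA37 (0.53) were above 0, and the others named in that list stayed below 0. Without 1 library the range crossed 0 for SNORD58B (-1.23 to 1.20), SNORD104 (-0.43 to 0.98), SCARNA9 (-0.47 to 0.79), RNU5D-1 (-0.18 to 0.79) and SNORA50 (-0.14 to 1.21), and the cause was not tested there or for the other changes without a stated reason. Depth limits the input side most, since 87 of the 140 features have fewer than 10 input reads.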

Other observations

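Some neighbouring snoRNAs lay far apart in level and ratio and others close together; the groups given here were chosen after their values were seen, their differences were not tested, and directions are on the authors' scale. Close together were SNORA5A and SNORA5C, at 7.71 and 7.60 RPKM in polyA-depleted RNA with log2 ratios of 2.79 and 2.84. Their neighbour SNORA5B lay apart from them, at 0 RPKM in input and 1.06 RPKM in polyA-depleted RNA with a log2 ratio of 1.04, under the mean RPKM minimum. Also close were SNORD12C and SNORD12B, at 10.5 and 12.6 RPKM with log2 ratios of 2.37 and 2.25, beside SNORD12 with a log2 ratio of 2.70. The members of each of these groups carry the same family name. How reads shared between similar copies were assigned is not given, so their levels may not be separate measurements. In the EIF4A2 region of chromosome 3, SNORA63 stood at 442 RPKM in polyA-depleted RNA between SNORA81 at 21.5 RPKM and SNORA4 at 20.4 RPKM, and the log2 ratios of the 3 were 5.30, 3.32 and 2.58. In the EIF4A1 region of chromosome 17, SNORD10 rose from 1.44 to 112 RPKM and SNORA48 from 3.57 to 34.6 RPKM, while SNORA67 was at 1.51 and 9.70 RPKM and did not pass (adjusted p = 0.0557 in limma). SNORD49B and SNORD49A of 1 host RNA rose from 55.9 to 143 RPKM and from 3.63 to 43.4 RPKM. SNORD102 rose from 0.483 to 42.6 RPKM and its neighbour SNORA27 from 0.851 to 18.7 RPKM. In the TAF1D region of chromosome 11, SNORA32 was the most abundant of 5 neighbours, at 9.71 and 48.3 RPKM, and SNORA25 at 4.28 and 9.89 RPKM did not pass (adjusted p = 0.0670 in limma). The neighbours said to rise passed an adjusted p of 0.05 in limma over the 140 features, and of them SNORD49B lost the call without the deeper (adjusted p = 0.0632) or the shallower input library (0.0610). Of the compared features named here, SNORA67, SNORD49B, SNORA32 and SNORA25 turned negative relative to the common shift, and after scaling to equal sums SNORA4, SNORD12B and SNORD12C were also below 0. SNORA5B, which was not compared, lay below the common shift too, with its log2 ratio of 1.04.

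Features of GAS5, SNHG7 and SNHG1 that kept the name of the host RNA, since no snoRNA was matched to them, also rose in limma past an adjusted p of 0.05. The 2 rows of GAS5 rose from 2.83 to 13.3 RPKM and from 1.62 to 11.7 RPKM, the 2 of SNHG7 from 5.07 to 52.2 RPKM and from 0.133 to 7.40 RPKM, and the 2 unmatched rows of SNHG1 from 3.69 to 24.2 RPKM and from 1.93 to 13.4 RPKM. The first GAS5 row lost its call without the deeper (adjusted p = 0.147) or the shallower input library (0.0810), and the second without the deeper input library (0.102), the deeper polyA-depleted library (0.0707) or the shallower one (0.0592). Both SNHG1 rows lost theirs without the deeper input library (adjusted p = 0.0767 and 0.0709), while those of SNHG7 passed in all 4 fits without 1 library. Relative to the common shift the first GAS5 row turned to -0.34, and after scaling to equal sums both rows of GAS5 and both of SNHG1 were below 0. Pseudogenes of snRNAs made up 73 rows, of which 7 were compared; over all 73 they held 164 input reads and 1211 polyA-depleted reads. Of the 150 features under the mean RPKM minimum, 70 were higher in polyA-depleted RNA, 31 lower and 49 at 0 reads in both groups.

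In what follows, all tests except those of poly(A) removal, host gene transcription and single library pairs were chosen after the result was seen. The first pattern is that 138 of 140 features were higher in polyA-depleted RNA. The filter on mean RPKM is argued against as the whole cause, since 96.4% of the 83 features picked on input RPKM alone were higher. The exact interval of 89.8% to 99.2% treats features as independent, though they share the same libraries and a shift of the whole table. Under the minimum 70 features were higher, 31 lower and 49 at 0 reads in both groups, so the filter does affect the share. A background that raises every feature by the same factor is argued against as the whole cause. The pooled rate ratio of the snRNA pseudogenes was 2.15 (interval 1.82 to 2.54), below the lower quartile of 4.83 of 21 H/ACA snoRNAs with 10 or more input reads. Pseudogene reads may be shared with snRNA genes, since the handling of such reads is not given. A background that adds the same RPKM to every feature would give unequal ratios, so the comparison cannot decide on it. That comparison does not cover unspliced host RNA, which reaches snoRNAs inside genes and need not reach these pseudogenes, so its part stays open. A single scaling factor is argued against as the whole cause by the class shares, which such a factor leaves as they are. The H/ACA share was 27.3% and 24.3% in the input libraries and 57.9% and 53.5% in the polyA-depleted libraries. The limma fit after centring, where 13 of 140 features passed, cannot decide this. On the log2(RPKM + 1) scale a single factor raises abundant features more than scarce ones, so some stay above the median after centring. With limma voom and centring 0 features passed (26 at an unadjusted p under 0.05). Removal of polyadenylated RNA, the nuclear extract and the library preparation cannot be told apart, because 0 groups share all but 1 of them.

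The second pattern is that the polyA-depleted libraries differed feature by feature, with an SD of 1.19 of their log2 ratio over 122 features with 50 or more reads, and 51 of them over 2-fold apart, while over the 16 features with 50 or more input reads the SD was 0.36 with 0 over 2-fold apart in input and 0.91 with 4 over 2-fold apart in polyA-depleted RNA. The variance over the 122 features was 22.2 times the counting variance, which separate samples can exceed for any reason, so it decides nothing about the cause. Length and GC content as the main cause are argued against, with Spearman's rho over features of -0.071 (bootstrap interval -0.25 to 0.12) for length and -0.13 (-0.34 to 0.09) for GC content, known for 82.8% of the features. Host gene transcription that differed between the samples stays open, as a hypothesis, since 51 neighbouring features in 20 clusters gave an intraclass correlation of 0.23 (bootstrap interval -0.07 to 0.50, permutation p = 0.0790). Features are not independent replicates in these tests, and each concerns these 2 libraries.

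The third pattern is that longer scaRNA features had larger ratios, with a rho of 0.90 and an r of 0.79 across 11 features, which are not independent replicates (permutation p = 0.00052 and 0.0030, adjusted over 5 classes 0.0026 and 0.015; r = 0.81 without the 2 features farthest from the median length). The 2 shortest rows, also those with the lowest ratios, are both listed under SCARNA9 and need not have the length of that RNA; without them rho was 0.83 and r 0.69 over 9 features (exact permutation p = 0.0083 and 0.047, adjusted over 5 classes 0.041 and 0.096; r = 0.63 without the 2 features farthest from the median length). The trend also rests on which rows count as scaRNAs. On chromosome X, 2 neighbouring rows with snoU2 names, of 71 and 81 bases, were classed as other. Their log2 ratios were 3.22 and 3.50, against 0.58 and 0.29 for the SCARNA9 rows of the same lengths. Whether they belong with the scaRNAs was not checked, and the trend was not computed with them. Counted as scaRNAs, short rows with ratios this large would weaken the trend. That 1 library pair carries the trend is argued against, since rho was 0.76 to 0.87 in the 4 pairs of an input and a polyA-depleted library, and 0.63 to 0.82 without SCARNA9. Size selection may still account for it: outside the scaRNAs rho was 0.13 (bootstrap interval -0.06 to 0.31), but only 6 of those 129 features reach the median scaRNA length of 188 bases and the longest has 207, so it cannot be told apart from a property of the scaRNAs.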
